A study of Mus musculus with 24 samples.

How the data were processed

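Gene expression was measured by RNA sequencing in 24 libraries of mouse MLL-AF9 leukaemia cells that express Cas9, in 8 groups of 3. The authors deposited raw read counts per gene for the whole series in a single table of 43629 Ensembl genes. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq and the tools HISAT2, HTSeq and DESeq2 were used with the mm10 build. Their versions, the annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. Each column of the table was assigned to its sample by name, and groups and replicate numbers were taken from the sample titles.

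Gene symbols, positions and types came from the GENCODE M21 annotation of GRCm38, the assembly that mm10 names. Of the 43629 identifiers, 42462 matched a symbol and 1167 had none. Library totals ranged from 2403044 to 7415397 counts. Replicates of a group were compared by a chi-square per gene over genes with at least 20 counts in the pair. It ranged from 4.76 to 34.31, so no libraries of a group differed by as little as sampling noise, and all 3 were counted in each group.

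Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3. Library sizes were scaled by TMM, genes with low counts were left out by edgeR's filter on groups (10578 genes stayed), and 1 quasi-likelihood fit held all 8 groups. They share 1 estimate of the spread because cells, day and protocol were the same. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. For MLLT10, MLLT1 and MLLT6, the mean of both guides was compared with the control, and each guide was also tested on its own. There were 19 comparisons: 4 of a knockout with the non-targeting control, 6 of a guide with the control, 3 between the guides of a gene and 6 between knockouts. Fold changes are log2 with a standard error (SE), worked back as the absolute log2 fold change over the square root of edgeR's F statistic. This SE is approximate and can be too small where a group holds few counts of a gene. Levels are TMM-normalised CPM (counts per 1e6 counts of a library), as mean ± SD. Where a group held no count of a gene, the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts, the ratio is given with its exact 95% interval, and both cover counting error only.

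Before the data were examined, 30 gene lists were fixed, with 608 distinct genes, each of which was found by symbol. Some genes are in several lists, as Hoxa9 is in those of MLL fusion targets, the Hoxa cluster and stem and progenitor genes. Results of such lists are therefore not separate. Lists with at least 5 tested members, 29 in each comparison, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted within a comparison, and repeated with the correlation estimated from the data. The comparisons, the test and the rule for named genes were also fixed then. That rule took the 5 genes of the DOT1L complex. It also took the 8 largest rises and falls among called genes with a mean of at least 5 CPM, in each main comparison. Where a gene had 2 guides, each guide had to pass in the same direction. Up to 4 members with the smallest adjusted p were named per list described, and the 3 largest rises and falls per comparison of knockouts. Symbols that are only clone or predicted names were skipped. Some genes that the rule took are not reported here.

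The alternatives tried were no filter on low counts, DESeq2 1.42.0 size factors, the DESeq2 test, the replicate number as a block, a fit of the compared groups alone, and leaving out each library in turn. Leaving out both libraries that stood apart was added after seeing the data. Whether replicate numbers pair the libraries was checked by the correlation across genes of their deviations from the group means. It exceeded 0.1 for each number in 6 of 28 pairs of groups. Among these were the non-targeting group with MLLT10 guide 1, with MLLT1 guide 2 and with MLLT6 guide 2.

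The fits were tested on simulated data with 50 genes changed at each fold size (1.5, 2, 4 and 8), all in the same simulation and none of low count. Where fewer genes change, a smaller share would be called. Of 2-fold changes, 52% were called for DOT1L, 80% for MLLT10, 62% for MLLT1 and 58% for MLLT6, each against non-targeting. Of 4-fold changes, 94% were called for DOT1L, 96% for MLLT10, 98% for MLLT1 and 98% for MLLT6. Between 1 and 7 unchanged genes were called among at least 10313 genes per simulated comparison. Because all 4 main comparisons share 3 control libraries, overlaps and correlations between them were set beside 40 simulations of unchanged groups. Figures and tables were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.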

Results

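RNA was sequenced from mouse acute myeloid leukaemia cells that carry the MLL-AF9 fusion oncogene and express Cas9. The cells received guide RNAs by lentivirus at an MOI of 0.3 and were selected for 72 hours with 2 ug/ml puromycin, from 48 hours after transduction. RNA was taken on day 9. The 24 libraries form 8 groups of 3: a non-targeting control, a DOT1L knockout, and 2 guides each for MLLT10, MLLT1 and MLLT6. The labels name no further guide for the DOT1L knockout or the control, so effects particular to a single guide cannot be told apart there. DOT1L is a histone methyltransferase, and the MLLT10, MLLT1 and MLLT6 proteins are known members of its complex. The comparisons ask which mRNAs differ when each member is targeted. Totals ranged from 2403044 to 7415397 counts per library. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

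The mRNA of the targeted gene was examined in every library first. Dot1l (ENSMUSG00000061589, mm10 chromosome 10, 80755206 to 80795461) stood at 49.1, 41.6 and 43.3 CPM in the DOT1L knockout and at 69.7, 75.1 and 73.9 CPM in the control. It fell by 0.71 ± 0.13 (SE) on the log2 scale (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.000189). Mllt10 (ENSMUSG00000026743, chromosome 2, 18055237 to 18212388) was at 9.06, 7.98 and 9.40 CPM with MLLT10 guide 1 and at 10.6, 11.1 and 12.1 CPM with guide 2. The control libraries held 16.9, 14.7 and 19.1 CPM, and the log2 fold change was -0.76 ± 0.21 (edgeR adjusted p = 0.139, and 0.0466 without both libraries that stood apart, MLLT1 guide 1 replicate 1 and MLLT6 guide 1 replicate 3, a choice made after the data were seen). Mllt6 (ENSMUSG00000038437, chromosome 11, 97663414 to 97685463) was at 20.9, 23.3 and 14.9 CPM with MLLT6 guide 1 and at 18.03, 19.07 and 17.08 CPM with guide 2. The control held 30.1, 42.2 and 32.7 CPM, and the log2 fold change was -0.90 ± 0.19 (edgeR adjusted p = 0.496, and 0.0274 with no filter on low counts).

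Mllt1 (ENSMUSG00000024212, chromosome 17, 56892611 to 56935415) was not lower in its own knockout. It was at 69.3, 46.1 and 36.7 CPM with MLLT1 guide 1, at 43.34, 48.46 and 34.95 CPM with guide 2 and at 41.2, 27.8 and 21.8 CPM in the control. The log2 fold change was 0.62 ± 0.22 (edgeR adjusted p = 0.148), and without non-targeting replicate 1 it was 0.89 (adjusted p = 0.0386). With the replicate number as a block it was 0.63 (adjusted p = 0.0471). The small insertions and deletions that Cas9 leaves need not lower an mRNA, and the guides' target sites are not given in the sources used here. The mRNA level therefore checks the knockout labels only weakly, and for MLLT1 it gives them no backing, so directions below refer to libraries as labelled.

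**Figure D1:**
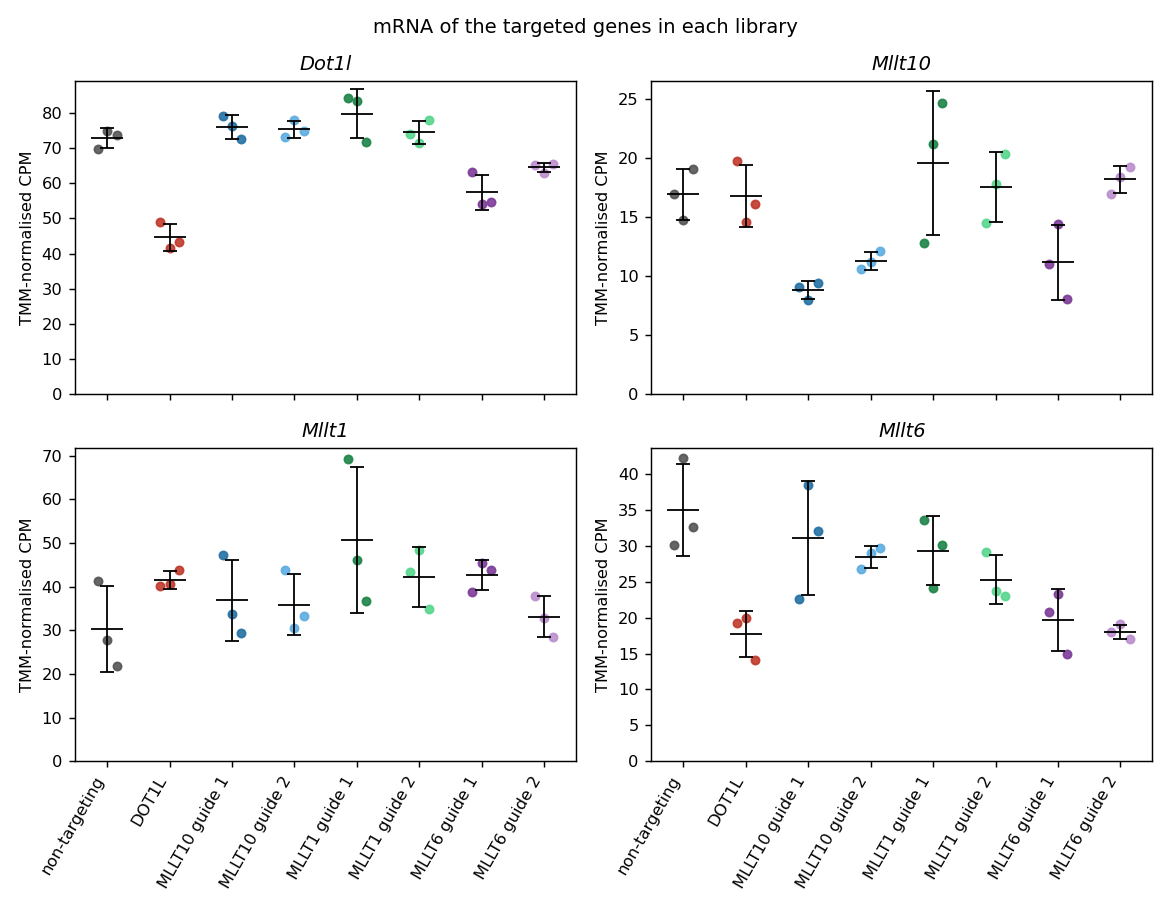
TMM-normalised CPM (linear axes from 0) of the 4 targeted genes in each of the 24 libraries, by group, where points are libraries and lines and bars are mean and SD. Dot1l lies between 41.6 and 49.1 CPM in the DOT1L knockout and between 69.7 and 75.1 CPM in the control, and Mllt1 is at 46.5 ± 12.4 CPM (n = 6) in the MLLT1 knockout beside 30.3 ± 9.95 CPM (n = 3) in the control.

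In the DOT1L knockout, genes of neutrophil granules rose by far more than in any other knockout, and genes that MLL fusions are known to drive fell. S100a8 (ENSMUSG00000056054, chromosome 3, 90668978 to 90670035), which encodes a subunit of the neutrophil protein calprotectin, rose from 70.8 ± 23.7 CPM (SD, n = 3) to 38750 ± 2570 CPM (n = 3). Its partner S100a9 rose from 63.8 ± 22.4 to 34800 ± 2720 CPM. Hoxa9 (ENSMUSG00000038227, chromosome 6, 52223100 to 52231089), a homeobox transcription factor, fell from 303 ± 54.0 to 62.9 ± 11.5 CPM. Meis1 (ENSMUSG00000020160, chromosome 11, 18879817 to 19018985), a cofactor of Hox proteins, fell from 94.96 ± 11.9 to 13.7 ± 6.56 CPM. Of 10578 genes tested, 1181 were higher and 1128 lower in the DOT1L knockout (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), 677 and 656 of them by at least 2-fold. S100a8 and S100a9 together took between 6.07% and 6.63% of all counts in the DOT1L libraries and between 0.011% and 0.019% in the control.

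Of the 26 tested neutrophil granule genes, 25 rose in the DOT1L knockout (camera adjusted p = 5e-83, and adjusted p = 2.2e-07 with an estimated correlation). Adjusted over the list alone, the same number rose. Ctsg, named after its value was seen, fell by 1.11 ± 0.17 (edgeR adjusted p = 4.4e-05). Camp, the antimicrobial peptide cathelicidin, rose from 62.7 ± 12.7 to 16200 ± 2380 CPM (log2 fold change 8.02 ± 0.34, edgeR adjusted p = 2.38e-14). Ltf, the iron-binding protein lactoferrin, rose by 11.15 ± 0.62 (adjusted p = 3.99e-12), and Fcnb, the granule lectin ficolin B, by 10.84 ± 0.55 (adjusted p = 6.04e-13). Stfa3, a cysteine protease inhibitor, rose by 11.40 ± 0.51 (adjusted p = 7.65e-14) and Wfdc21 by 10.10 ± 0.38 (adjusted p = 6.99e-15). Chil3, a chitinase-like protein of myeloid cells, had 18965 counts against 1, a ratio of 1.4e+04 with a 95% counting interval from 2.51e+03 to 5.52e+05. Retnlg was at least 170-fold higher and Erc2, known as a presynaptic scaffold gene, at least 68.6-fold higher than in a control group without a count. Stfa2, Stfa3, Chil3, Lyz2 and Hbb-bt have close paralogs whose reads the counting could have split, so their levels are uncertain.

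Of 20 tested monocyte and macrophage genes, 9 rose and 3 fell in the DOT1L knockout (camera adjusted p = 3.1e-06, and adjusted p = 0.0041 with an estimated correlation). Adjusted over the list alone, 9 rose and 4 fell. Cybb, the large subunit of the phagocyte NADPH oxidase, rose by 10.36 ± 0.44 (edgeR adjusted p = 3.2e-14). Lyz2, lysozyme, rose from 58.9 ± 5.34 to 2887 ± 591 CPM. Adgre1, which encodes the macrophage marker F4/80, fell from 220 ± 53.4 to 39.1 ± 6.83 CPM. Of 18 myeloid transcription factors, 9 rose and 1 fell (adjusted p = 0.011, and adjusted p = 0.084 with an estimated correlation). Adjusted over the list alone, 10 rose and 1 fell, and in a fit of the compared groups alone 9 rose and 2 fell. Cebpd rose by 2.29 ± 0.26, Spi1 by 1.38 ± 0.23 and Klf6 by 2.59 ± 0.45, and Irf8, a factor of monocyte and dendritic cell development, fell by 1.75 ± 0.26 (largest edgeR adjusted p of these, 0.000148). Of 9 macrophage cytokine genes, 3 rose and 1 fell (camera adjusted p = 0.0036, and adjusted p = 0.074 with an estimated correlation), as also when adjusted over the list alone. The fall, that of Osm (edgeR adjusted p = 0.027), was lost without non-targeting replicate 3 (0.118) or DOT1L replicate 1 (0.0689) or 3 (0.13), and 2 genes fell without non-targeting replicate 1, with the DESeq2 test or with no filter on low counts. Il1rn, the interleukin-1 receptor antagonist, rose by 5.14 ± 0.34, and Ccl6, a chemokine, by 4.96 ± 0.47 (edgeR adjusted p = 2.9e-08).

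Of 26 tested MLL fusion target genes, 17 fell and 1 rose in the DOT1L knockout (camera adjusted p = 1.9e-19, and adjusted p = 0.0014 with an estimated correlation). Adjusted over the list alone, 19 fell and 2 rose. All 6 tested genes of the Hoxa cluster fell (camera adjusted p = 6e-14, and adjusted p = 0.0013 with an estimated correlation), as also when adjusted over the list alone. The log2 fold changes were -2.90 ± 0.24 for Hoxa10, -2.65 ± 0.21 for Hoxa11, -2.27 ± 0.19 for Hoxa9 and -2.19 ± 0.20 for Hoxa5 (largest edgeR adjusted p of these, 2.19e-08). Meis1 fell by 2.83 ± 0.22 (adjusted p = 1.2e-09). Cdkn2c, a cyclin-dependent kinase inhibitor, fell from 192 ± 20.9 to 34.99 ± 9.33 CPM. Of 23 stem and progenitor genes, 11 fell and 2 rose (adjusted p = 1.9e-09, and adjusted p = 0.00014 with an estimated correlation). Adjusted over the list alone, 13 fell and 2 rose. Without non-targeting replicate 2 or 3, 1 rose. Muc13 fell by 2.26 ± 0.19, and Cd93, a receptor of early haematopoietic cells, fell by 1.64 ± 0.14 (edgeR adjusted p = 6.39e-09).

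**Figure D2:**
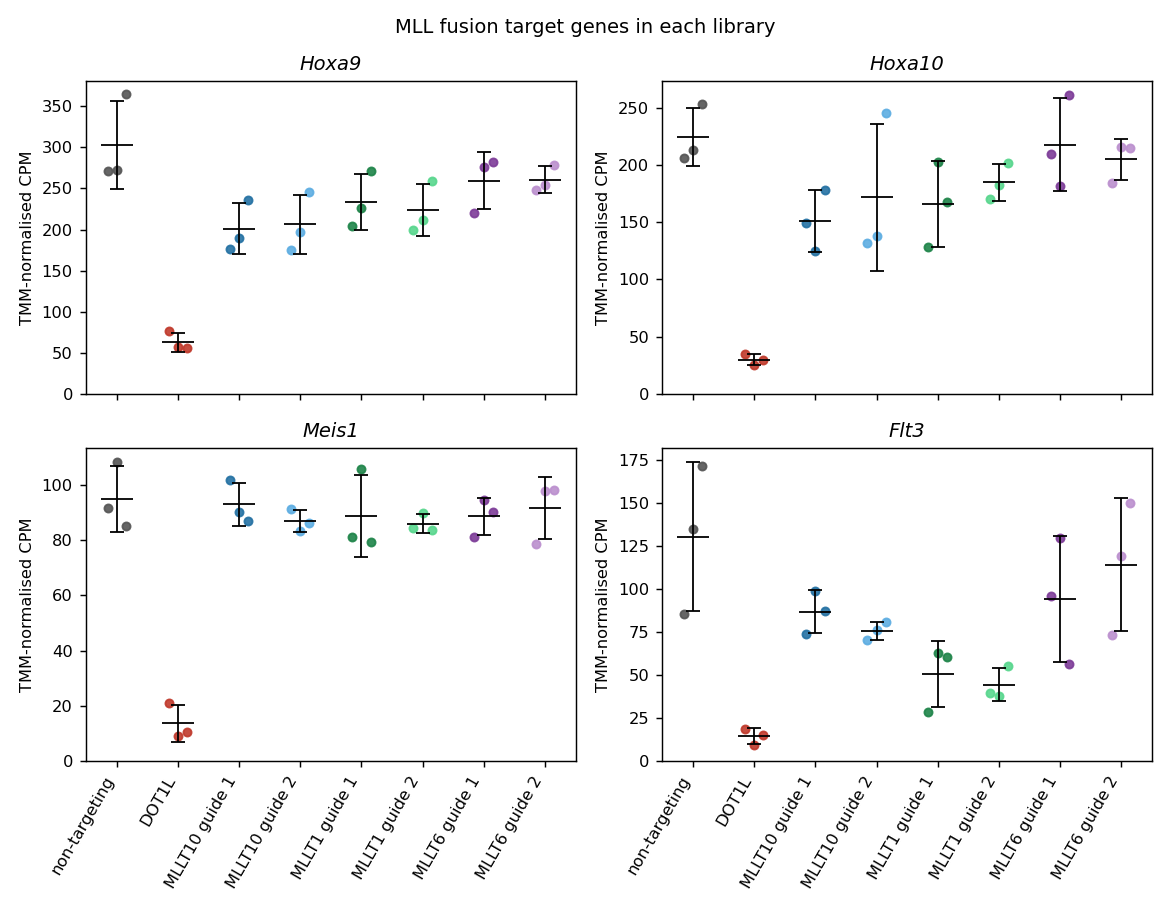
TMM-normalised CPM (linear axes from 0) of the MLL fusion target genes Hoxa9, Hoxa10, Meis1 and Flt3 in each of the 24 libraries, by group, where points are libraries and lines and bars are mean and SD. Hoxa9 is at 62.9 ± 11.5 CPM (n = 3) in the DOT1L knockout, 204 ± 30.2 (n = 6) in MLLT10, 229 ± 29.9 (n = 6) in MLLT1, 260 ± 24.2 (n = 6) in MLLT6 and 303 ± 54.0 (n = 3) in the control.

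Genes of other blood lineages moved as well in the DOT1L knockout, though Flt3 is also in the lists of MLL fusion targets and of stem and progenitor genes. Of 5 dendritic cell genes, 4 fell (camera adjusted p = 9.3e-06, and adjusted p = 0.0085 with an estimated correlation), as also when adjusted over the list alone. Flt3, a cytokine receptor of progenitors, fell by 3.16 ± 0.36, and Tcf4 fell by 2.23 ± 0.24 (largest edgeR adjusted p of both, 4.8e-07). Of 8 class II antigen presentation genes, 5 fell (camera adjusted p = 0.00093, and adjusted p = 0.051 with an estimated correlation), as also over the list alone. H2-Ob fell by 3.83 ± 0.33, and H2-DMa fell by 1.74 ± 0.32 (adjusted p = 0.000254). Of 6 mast cell and basophil genes, 3 fell (camera adjusted p = 0.042, and adjusted p = 0.084 with an estimated correlation), as also over the list alone. Gata2 fell by 2.33 ± 0.28, and Cpa3, a mast cell protease, fell by 4.12 ± 0.63 (adjusted p = 3.33e-05). Large falls outside the lists were those of Cbr2, Tnfrsf9, Stc1, Lypd6b, Platr26 and C2cd4b. Cbr2, a carbonyl reductase, was at least 45.2-fold lower, with no count in the knockout. Tnfrsf9, a costimulatory receptor, fell from 1189 ± 402 to 9.57 ± 8.81 CPM (log2 fold change -6.82 ± 0.69, adjusted p = 8.79e-08). Stc1 had a log2 fold change of -5.04 ± 0.61, Lypd6b of -4.80 ± 0.60, Platr26 of -4.40 ± 0.38 and C2cd4b of -4.30 ± 0.40 (largest adjusted p of these, 2.14e-06).

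Lists of genes of growth and metabolism were also tested in the DOT1L knockout. Of 32 DNA replication genes, 6 rose (camera adjusted p = 0.023, and adjusted p = 0.19 with an estimated correlation), and 5 when adjusted over the list alone. The count of 6 was 3 without non-targeting replicate 2 or 3 or DOT1L replicate 1 or 3, and in a fit of the compared groups alone. With the replicate number as a block and without both libraries that stood apart it was 10. Rrm2, a subunit of ribonucleotide reductase, rose by 0.98 ± 0.14 and Mcm5 by 0.58 ± 0.15 (edgeR adjusted p = 0.00642). Of 29 mitosis genes, 6 rose (camera adjusted p = 0.042, and adjusted p = 0.21 with an estimated correlation), and 7 when adjusted over the list alone. It was 2 without non-targeting replicate 1, 1 without DOT1L replicate 3, and 3 without non-targeting replicate 2 or 3 or DOT1L replicate 1, with no filter on low counts or in a fit of the compared groups alone. With the replicate number as a block the mitosis count was 9, and 11 when both libraries that stood apart were also left out. Mki67, a proliferation marker, rose by 0.84 ± 0.22 (edgeR adjusted p = 0.0083). Of 17 glycolysis genes, 7 fell (camera adjusted p = 0.0032, and adjusted p = 0.15 with an estimated correlation), and 9 when adjusted over the list alone. It was 4 without non-targeting replicate 2 and 3 without DOT1L replicate 1. Pdk1 had a log2 fold change of -1.28 ± 0.18, Pfkm of -1.62 ± 0.24 and Pfkp of -0.84 ± 0.19 (largest edgeR adjusted p of these, 0.0024). Of 32 ribosomal protein genes, 3 fell, and none when adjusted over the list alone (camera adjusted p = 0.018, and adjusted p = 0.45 with an estimated correlation). The count of 3 was 6, 0 and 1 without non-targeting replicates 1, 2 and 3, and 1 and 0 without DOT1L replicates 1 and 3. It was 7 in a fit of the compared groups alone. In all, 14 of 29 lists passed with the preset correlation and 6 with an estimated one. Each of the 71 named genes that passed lay on the same side of the control mean in all 3 DOT1L libraries. Selection by the test on these same libraries favours this, so it is no separate evidence.

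The MLLT10 knockout raised some of the neutrophil genes that rose in the DOT1L knockout, to far lower levels. S100a8 rose from 70.8 ± 23.7 CPM (n = 3) to 273 ± 73.2 CPM (n = 6), and Mpo, the granule enzyme myeloperoxidase, from 341 ± 61.4 to 854 ± 107 CPM. Lpxn, a focal adhesion protein, fell from 76.3 ± 9.86 to 22.9 ± 5.37 CPM. Across all genes, 25 were higher and 25 lower (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), 22 and 10 of them by at least 2-fold. Dot1l was at 75.7 ± 2.65 CPM beside 72.9 ± 2.84 CPM in the control (edgeR adjusted p = 0.916).

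The largest rises that both MLLT10 guides shared were those of Wfdc21, Mgl2, S100a8, S100a9, Prom1, Ube4a, Mpo and Ccl9. Wfdc21 rose by 3.50 ± 0.37 (edgeR adjusted p = 2.08e-05), Mgl2, a macrophage lectin, by 2.20 ± 0.34 (adjusted p = 0.00151) and S100a9 by 1.81 ± 0.24 (adjusted p = 0.000465). Ccl9, a chemokine, rose by 1.06 ± 0.17 (adjusted p = 0.00178), Prom1, which encodes CD133, by 1.70 ± 0.30 (adjusted p = 0.00687) and Ube4a by 1.36 ± 0.25 (adjusted p = 0.00721). Among the falls that both guides shared were those of Lpxn (-1.74 ± 0.20), Pan3, a deadenylase subunit (-1.04 ± 0.16), and the kinase gene Wnk1 (-0.80 ± 0.12, largest adjusted p of these, 0.00178). Prom1 and Ube4a no longer passed without non-targeting replicate 2 (adjusted p = 0.125 and 0.135) or replicate 3 (adjusted p = 0.104 and 0.0949), nor in a fit of the compared groups alone (adjusted p = 0.074 and 0.0946). Each of the 16 named genes that passed lay on the same side of the control mean in all 6 MLLT10 libraries, which again follows largely from their selection.

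Of 26 neutrophil granule genes, 7 rose and none fell in the MLLT10 knockout (camera adjusted p = 4.6e-22, and adjusted p = 0.00095 with an estimated correlation), and 15 rose when adjusted over the list alone. The 7 were 3 without non-targeting replicate 2 or 3 and 14 with no filter on low counts. Of 9 macrophage cytokine genes, 1 rose, Ccl9, and 3 when adjusted over the list alone (adjusted p = 3.3e-05, and adjusted p = 0.041 with an estimated correlation), with the DESeq2 test or with no filter. Of 26 MLL fusion targets, 1 fell, and 4 when adjusted over the list alone (adjusted p = 4.3e-07, and adjusted p = 0.065 with an estimated correlation). With the DESeq2 test or the replicate number as a block 3 fell, and with no filter 5. The gene called by edgeR in the fit of all libraries was Pbx3, a partner of Hox proteins, with a log2 fold change of -0.72 ± 0.16 (edgeR adjusted p = 0.0464), which passed neither without non-targeting replicate 2 (adjusted p = 0.183) nor without replicate 3 (adjusted p = 0.377). It also did not pass without MLLT10 guide 1 replicate 1 (adjusted p = 0.114) or 3 (0.0698), or without guide 2 replicate 1 (0.126) or 2 (0.0945), nor in a fit of the compared groups alone (0.154). None of the 6 Hoxa genes passed over all genes, and 4 fell when adjusted over the list alone (camera adjusted p = 3.3e-05, and adjusted p = 0.057 with an estimated correlation). Hoxa9 was at 204 ± 30.2 CPM (n = 6) beside 303 ± 54.0 CPM (n = 3), with an edgeR adjusted p of 0.0975. That p was 0.0257 with the replicate number as a block in all groups, and 0.0222 with the DESeq2 test. Of 6 mast cell and basophil genes, 1 fell, and 2 over the list alone (camera adjusted p = 0.016, and adjusted p = 0.057 with an estimated correlation). That gene, Cpa3, did not pass without non-targeting replicate 1 (edgeR adjusted p = 0.08) or 3 (0.0864).

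No gene of 3 further lists passed edgeR's test over all genes in the MLLT10 knockout, though camera called the lists. The 32 DNA replication genes lay higher (adjusted p = 0.00028, and adjusted p = 0.057 with an estimated correlation), with 2 rises when adjusted over the list alone. Over all genes, Rrm2 passed without non-targeting replicate 1 (edgeR adjusted p = 0.0207) and with the DESeq2 test (0.0116), and Uhrf1 with the DESeq2 test (0.0291) and with no filter on low counts (edgeR adjusted p = 0.0123). The 32 Myc and ribosome biogenesis genes also lay higher (adjusted p = 0.039, and adjusted p = 0.59 with an estimated correlation). The 32 ribosomal protein genes lay lower (adjusted p = 0.027, and adjusted p = 0.48 with an estimated correlation), and with no filter 2 of them fell. Of 20 monocyte and macrophage genes, 1 fell, Adgre1 (camera adjusted p = 0.13), and 2 also rose with no filter. Its edgeR adjusted p of 0.00721 was 0.115 without non-targeting replicate 2, 0.161 without replicate 3 and 0.0622 in a fit of the compared groups alone. Of 23 stem and progenitor genes, 1 rose, Prom1 (camera adjusted p of the list, 0.065), and none without non-targeting replicate 2 or 3. Prom1 did not pass in a fit of the compared groups alone (edgeR adjusted p = 0.074), and without MLLT10 guide 1 replicate 3, Ikzf2 also fell (edgeR adjusted p = 0.0195). With no filter, the DESeq2 test or the block, 2 of the list fell. The count of 50 called genes was 15 without non-targeting replicate 2, 15 without replicate 3, 33 without MLLT10 guide 1 replicate 1 and 79 without both libraries that stood apart. It was 192 with no filter on low counts, 102 with the DESeq2 test, 79 with the replicate number as a block and 28 in a fit of the compared groups alone.

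**Figure D3:**
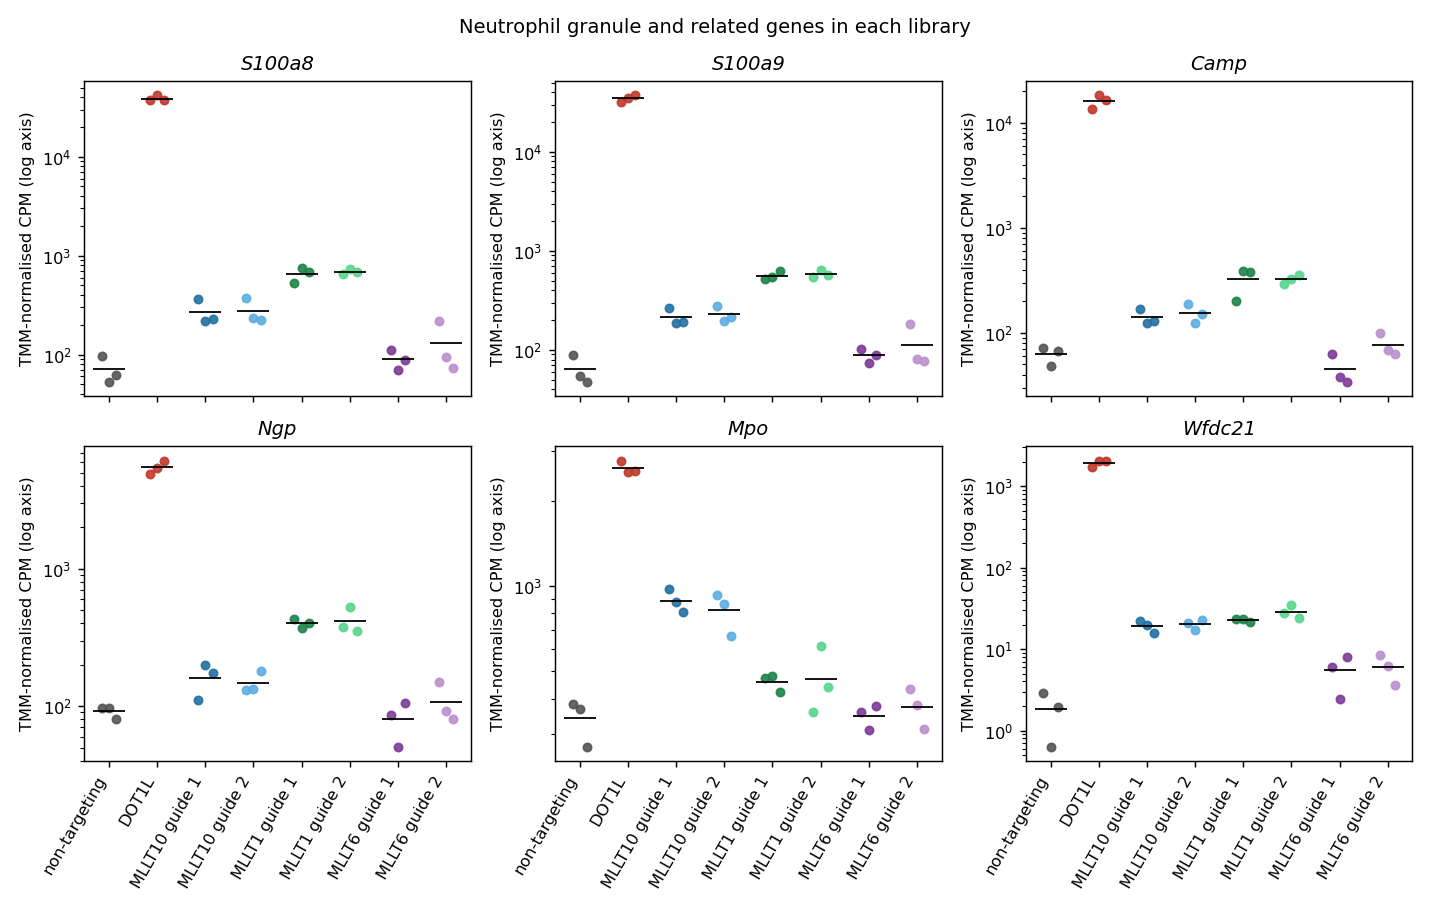
TMM-normalised CPM (log axes) of 6 neutrophil and related genes in each of the 24 libraries, by group, where points are libraries and lines are group means. S100a8 is at 70.8 CPM in the control, 110 in MLLT6, 273 in MLLT10, 669 in MLLT1 and 38750 in the DOT1L knockout, as means over 3 or 6 libraries.

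In the libraries labelled MLLT1 knockout, S100a8 and other neutrophil granule genes rose, and Tnfrsf9 fell. S100a8 rose from 70.8 ± 23.7 CPM (n = 3) to 669 ± 80.5 CPM (n = 6) and S100a9 from 63.8 ± 22.4 to 575 ± 48.9 CPM. Tnfrsf9 fell from 1189 ± 402 to 69.5 ± 42.4 CPM, and Hbb-bt, an adult beta-globin, from 77.4 ± 14 to 13.3 ± 4.16 CPM. Hoxa9 was at 229 ± 29.9 CPM beside 303 ± 54.0 CPM in the control (edgeR adjusted p = 0.175). Across all genes, 103 were higher and 170 lower (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), 57 and 96 of them by at least 2-fold.

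The largest rises that both MLLT1 guides shared were those of Ltf, by 4.21 ± 0.66 (edgeR adjusted p = 0.000696), Wfdc21, by 3.87 ± 0.36, and Clec4a2, a lectin receptor of myeloid cells, by 3.28 ± 0.44. S100a8 rose by 3.24 ± 0.32, S100a9 by 3.18 ± 0.26 and Camp by 2.38 ± 0.25 (adjusted p = 2.32e-06). Chil1, a chitinase-like protein, rose by 2.88 ± 0.55 (adjusted p = 0.00428, and 0.0534 without non-targeting replicate 2), and Cd177, a neutrophil surface protein, by 2.41 ± 0.39 (adjusted p = 0.00111). Among the largest shared falls were those of Tnfrsf9 (-4.11 ± 0.45), Ddx4, an RNA helicase of germ cells (-2.74 ± 0.26), and Hbb-bt (-2.57 ± 0.23, largest adjusted p of these, 4.29e-06). Il2ra, the alpha chain of the interleukin-2 receptor, had a log2 fold change of -2.28 ± 0.36 and Tslp, a cytokine, of -2.15 ± 0.29 (largest adjusted p of these, 0.000766). Stc1 fell by 2.16 ± 0.39 (adjusted p = 0.00269, and 0.0511 without non-targeting replicate 3). Of the 26 named genes that passed, 25 lay on the same side of the control mean in all 6 MLLT1 libraries, and Lmo2 did so in 5 of 6. That too follows largely from how the genes were selected.

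Of 26 neutrophil granule genes, 13 rose and 2 fell in the MLLT1 knockout (camera adjusted p = 1.1e-21, and adjusted p = 0.00096 with an estimated correlation). Adjusted over the list alone, 15 rose and 3 fell. The 13 rises were 8 without non-targeting replicate 2. Ngp, a granule protein, rose from 91.5 ± 8.86 to 409 ± 62.8 CPM (log2 fold change 2.16 ± 0.24, edgeR adjusted p = 6.92e-06). The 2 that fell, named after their values were seen, were the serine protease genes Prtn3 (log2 fold change -0.58 ± 0.15) and Ctsg (-0.83 ± 0.14, edgeR adjusted p = 0.0329 and 0.00187). Of the list, 1 gene fell without non-targeting replicate 2 or 3, MLLT1 guide 1 replicate 1 or 2, or guide 2 replicate 1 or 2, and in a fit of the compared groups alone. Of 20 monocyte and macrophage genes, 2 rose and 2 fell (camera adjusted p = 0.35), and 6 rose and 3 fell when adjusted over the list alone. Without non-targeting replicate 2 or 3, or in a fit of the compared groups alone, 1 rose and 1 fell, and without MLLT1 guide 2 replicate 1, 1 fell. With the DESeq2 test or the replicate number as a block 4 rose, and with no filter 5. Clec4a2 rose from 1.51 ± 0.89 to 15.6 ± 2.75 CPM, and Adgre1 fell from 220 ± 53.4 to 118 ± 16.4 CPM.

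Of 26 MLL fusion targets, 1 fell in the MLLT1 knockout, and 2 when adjusted over the list alone, with the DESeq2 test or with the replicate number as a block (camera adjusted p = 0.28). The gene that fell in each, Flt3, fell by 1.46 ± 0.26 (edgeR adjusted p = 0.00269, and 0.0548 without non-targeting replicate 3). None of the 6 Hoxa genes passed, over all genes or over the list alone (camera adjusted p = 0.36). Of 23 stem and progenitor genes, 2 rose and 3 fell (camera adjusted p = 0.49, direction down with a median log2 fold change of 0.06), and 3 rose and 5 fell when adjusted over the list alone. None rose without non-targeting replicate 2 or 3, where 2 and 1 fell, and 1 rose and 2 fell without MLLT1 guide 1 replicate 2 or 3 or guide 2 replicate 1 or 3. In a fit of the compared groups alone none rose and 2 fell. Muc13 fell by 0.81 ± 0.16 (edgeR adjusted p = 0.00417). Of 32 DNA replication genes, 1 rose, and 5 when adjusted over the list alone (camera adjusted p = 6e-05, and adjusted p = 0.058 with an estimated correlation). That gene, E2f1, had an edgeR adjusted p of 0.0432. It did not pass without non-targeting replicate 2 (0.342) or 3 (0.236), MLLT1 guide 1 replicate 1 (0.0671) or 2 (0.0877), or guide 2 replicate 1 (0.053) or 2 (0.116), nor in a fit of the compared groups alone (0.179). Without non-targeting replicate 1, 4 passed. Rrm2, Uhrf1 and Tyms also rose with the replicate number as a block (edgeR adjusted p = 0.0397, 0.0394 and 0.0471), as with the DESeq2 test (0.0214, 0.0297 and 0.048), and with no filter Uhrf1 did (edgeR adjusted p = 0.0203).

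Other lists moved in the MLLT1 knockout with few or no called genes. The 32 ribosomal protein genes lay lower (adjusted p = 0.0029, and adjusted p = 0.53 with an estimated correlation) and the 32 Myc and ribosome biogenesis genes higher (adjusted p = 0.043, and adjusted p = 0.56 with an estimated correlation), with none called by edgeR in the fit of all libraries without a block. Rrp12 (log2 fold change 0.87, edgeR adjusted p = 0.0206) and Nop2 (0.63, adjusted p = 0.0311) rose with the replicate number as a block in all groups. With no filter Rrp12 (edgeR adjusted p = 0.0354) and 1 ribosomal protein gene were called. Without non-targeting replicate 1, 3 of the Myc and ribosome biogenesis genes were called, and without MLLT1 guide 1 replicate 1, 1 of the ribosomal protein genes. Of 12 immediate early genes, 1 fell, over all genes and over the list alone (adjusted p = 0.043, and adjusted p = 0.53 with an estimated correlation). That gene, Dusp2, did not pass without non-targeting replicate 2 (edgeR adjusted p = 0.177) or 3 (0.169), nor in a fit of the compared groups alone (0.109), and Ier3 also fell with the block (0.0353) and with no filter (0.0442). The count of 273 called genes was 432 without non-targeting replicate 1, 83 without replicate 2 and 74 without replicate 3. It was 463 with no filter on low counts, 457 with the replicate number as a block and 97 in a fit of the compared groups alone.

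No gene passed the test in the MLLT6 knockout. S100a8 was at 110 ± 56.0 CPM (n = 6) beside 70.8 ± 23.7 CPM (n = 3) in the control, and Hoxa9 at 260 ± 24.2 CPM beside 303 ± 54.0 CPM. Mllt6 itself was at 18.9 ± 2.94 CPM beside 34.99 ± 6.39 CPM, lower in 6 of 6 libraries. It was as low in the DOT1L knockout (19.3, 19.9 and 14.1 CPM), where it was called lower, so a low level is not particular to the MLLT6 knockout. Dot1l was at 61.0 ± 5.15 CPM beside 72.9 ± 2.84 CPM (edgeR adjusted p = 0.699). The count was 0 with edgeR's quasi-likelihood test after Benjamini-Hochberg adjustment (smallest adjusted p = 0.50, 727 genes at an unadjusted p under 0.05). The 727 were 1256 without non-targeting replicate 1, 258 without replicate 3 and 472 without MLLT6 guide 1 replicate 3. It was also 0 with DESeq2, with 798 genes at an unadjusted p under 0.05, and 80 with no filter on low counts.

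No gene of the 26 neutrophil granule genes or of the 6 Hoxa genes passed in the MLLT6 knockout, over all genes or over the list alone (camera adjusted p = 0.89 and 0.81). S100a9 had a log2 fold change of 0.65 ± 0.24 (edgeR adjusted p = 0.699, and 0.0469 with no filter on low counts) and Hoxa5 of -0.24 ± 0.16 (adjusted p = 0.738). With both guides together none of 29 lists passed. The smallest camera adjusted p, 0.095, was that of the 23 ATF4 and amino acid response genes, of which none was called. With the replicate number as a block it was 0.046. With guide 2 on its own this list passed, higher than the control (camera adjusted p = 0.0037, and adjusted p = 0.55 with an estimated correlation), and with guide 1 on its own it did not (0.46). In the library of MLLT6 guide 1 replicate 3, which stood apart from its group, pseudogenes took 3.08% of counts, against 2.15% or less in the other 23 libraries.

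**Figure D4:**
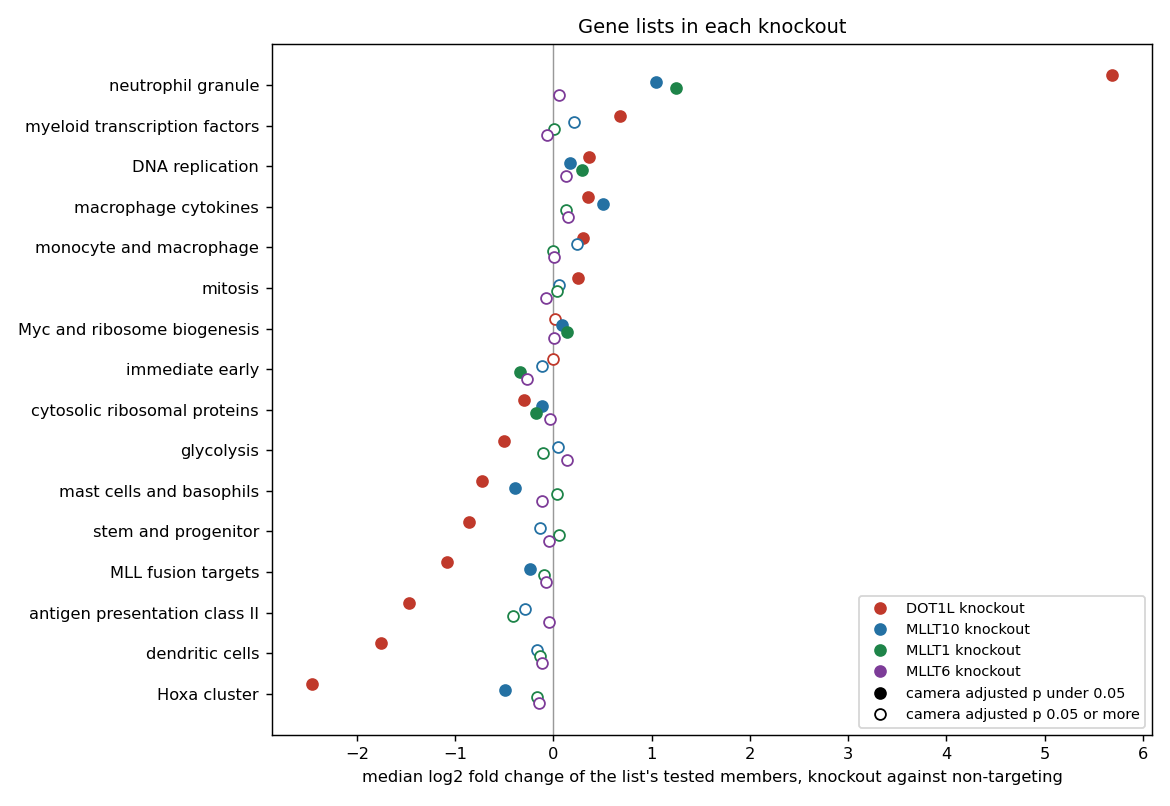
Median log2 fold change against non-targeting (x axis) of the tested members of each gene list (y axis) that passed camera in any of the 4 knockouts, with filled points at an adjusted p under 0.05. The Hoxa cluster lies at -2.46 in the DOT1L knockout, -0.49 in MLLT10, -0.17 in MLLT1 and -0.15 in MLLT6.

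Tested guide by guide, both MLLT10 guides raised Wfdc21, S100a8 and S100a9. Wfdc21 rose by 3.47 with guide 1 and by 3.53 with guide 2 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 7.59e-05 and 5.39e-05). Mpo rose by 1.38 and 1.26 (adjusted p = 0.000677 and 0.0013). MLLT10 guide 1 gave 12 higher and 6 lower genes, and guide 2 gave 22 higher and 10 lower. Of the 18 genes called with guide 1, 16 were called in the same direction with guide 2. With the replicate number as a block in all groups, the guide 1 count was 30. Without 1 library it was 7 (non-targeting replicate 2), 5 (non-targeting replicate 3) or 9 (guide 1 replicate 1). The guide 2 count was 50, 6 and 5 without non-targeting replicates 1, 2 and 3, and 19, 18 and 15 without its own replicates 1, 2 and 3.

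Both MLLT1 guides raised S100a9 and Camp and lowered Tnfrsf9. S100a9 rose by 3.14 with guide 1 and by 3.21 with guide 2 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 7.87e-07 and 5.57e-07). Tnfrsf9 had log2 fold changes of -4.19 and -4.02 (adjusted p = 0.000304 and 0.000442). MLLT1 guide 1 gave 62 higher and 70 lower genes, and guide 2 gave 52 higher and 77 lower. Of the 132 genes called with guide 1, 88 were called in the same direction with guide 2 and none in the opposite one. With the replicate number as a block in all groups, the guide 1 count was 265 and the guide 2 count was 223. The guide 1 count was 265, 37 and 39 without non-targeting replicates 1, 2 and 3, and 75, 49 and 71 without its own. The guide 2 count was 215, 44 and 49 without the same controls, and 62, 47 and 74 without its own replicates.

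Neither MLLT6 guide gave a called gene. S100a8 had a log2 fold change of 0.35 with guide 1 and 0.87 with guide 2 (edgeR adjusted p = 0.639 and 1). With guide 2 it stood at 219.66, 95.3 and 72.8 CPM in replicates 1, 2 and 3, beside 97.7, 53.2 and 61.4 CPM in the control. The guide 2 value thus rests mostly on replicate 1. With edgeR, 1389 genes were at an unadjusted p under 0.05 with guide 1 and 286 with guide 2. The 1389 were 672 without non-targeting replicate 3 and 567 without guide 1 replicate 3, and the 286 were 661 without non-targeting replicate 1 and 189 without replicate 3. DESeq2 called 47 genes with guide 1, 38 higher and 9 lower, and 0 with guide 2. The edgeR count for guide 1 was 31 without its replicate 1, 1 without its replicate 2 and 291 with no filter on low counts, and for guide 2 it was 19 with no filter.

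The guides of a gene were also compared with each other. S100a8, at log2 fold changes of 1.93 and 1.97 with the MLLT10 guides and of 3.22 and 3.27 with the MLLT1 guides, was not called between guides. No gene was called between guides of MLLT10, MLLT1 or MLLT6 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), with 182, 222 and 983 genes at an unadjusted p under 0.05. The 182 were 518 and 91 without MLLT10 guide 1 replicates 1 and 2, and 462 and 79 without guide 2 replicates 1 and 3. The 222 were 565 without MLLT1 guide 1 replicate 3, and the 983 were 1508 and 434 without MLLT6 guide 1 replicates 1 and 3. DESeq2 called 0, 0 and 10. With no filter on low counts edgeR called 16, 21 and 67. Without 1 library, 1 gene was called between the MLLT10 guides (without guide 2 replicate 1, and without guide 2 replicate 3) and 1 between the MLLT6 guides (without guide 1 replicate 1).

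Set directly against the DOT1L knockout, the MLLT10 knockout had far less Chil3, Stfa3 and Ifitm6 and more Tnfrsf9. Chil3 was at 1.76 ± 1.5 CPM (n = 6) in MLLT10 and at 1783 ± 340 CPM (n = 3) in DOT1L, Stfa3 at 4.69 ± 1.84 against 2046 ± 106 CPM, and Ifitm6 at 0.27 ± 0.17 against 104 ± 19.7 CPM. Tnfrsf9 was at 319 ± 140 against 9.57 ± 8.81 CPM and Hbb-bt at 47.6 ± 15.7 against 2.04 ± 0.72 CPM. Hoxc4, a homeobox gene, had a ratio of 26.5 with a 95% counting interval from 8.95 to 129. The test called 1153 genes higher and 1333 lower in MLLT10 than in DOT1L (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

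The MLLT1 knockout likewise had far less Chil3 and Fcnb than the DOT1L knockout. Chil3 was at 1.35 ± 1.49 CPM (n = 6) in MLLT1 against 1783 ± 340 CPM (n = 3), and Fcnb at 6.22 ± 2.41 against 1621 ± 179 CPM. Higher in MLLT1 were Parm1, by 4.27 ± 0.84, Itga2b, an integrin of megakaryocytes, by 3.75 ± 0.69, and the collagen gene Col4a1, by 3.73 ± 0.43 (edgeR adjusted p = 0.000545, 0.000294 and 5.46e-07). In all, 898 genes were higher and 1176 lower in MLLT1 than in DOT1L.

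The MLLT6 knockout differed most from the DOT1L knockout by count. Tnfrsf9 was at 1289 ± 316 CPM (n = 6) in MLLT6 against 9.57 ± 8.81 CPM (n = 3). Cbr2 was at least 32.8-fold higher in MLLT6, Retnlg at least 447-fold lower, and C5ar1, a complement receptor, at least 322-fold lower. The test called 1484 genes higher and 1616 lower in MLLT6 than in DOT1L (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

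Between the MLLT10 and MLLT1 knockouts, F13a1, which encodes a coagulation factor subunit, was at 73.3 ± 18.8 CPM (n = 6) in MLLT10 and at 15.4 ± 5.41 CPM (n = 6) in MLLT1. Tnfrsf9 was at 319 ± 140 against 69.5 ± 42.4 CPM. Lower in MLLT10 were Itga2b (log2 fold change -2.32 ± 0.44), Ly6g5b (-1.84 ± 0.30) and Clec4a2 (-1.74 ± 0.25, edgeR adjusted p = 0.00271, 0.000603 and 0.000166). In all, 158 genes were higher and 125 lower in MLLT10 than in MLLT1, 434 in both directions with the replicate number as a block.

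Between the MLLT10 and MLLT6 knockouts, Mgl2 was at 46.5 ± 17.3 CPM (n = 6) in MLLT10 and at 12.04 ± 3.32 CPM (n = 6) in MLLT6, and Ccl6 at 11.1 ± 4.39 against 2.70 ± 1.35 CPM. Fcnb was also higher in MLLT10, by 1.92 ± 0.35 (edgeR adjusted p = 0.00671, and 0.0626 in a fit of the compared groups alone). Lower in MLLT10 were Tnfrsf9 (log2 fold change -2.00 ± 0.38), Abcb4, a phospholipid transporter (-1.92 ± 0.28), and Lpxn (-1.71 ± 0.18, adjusted p = 0.00848, 0.000534 and 9.57e-06). In all, 44 genes were higher and 37 lower. The count of 81 was 52 and 53 without MLLT10 guide 1 replicates 2 and 3, 50, 53 and 50 without guide 2 replicates 1, 2 and 3, and 45 and 46 without MLLT6 guide 2 replicates 2 and 3. It was 272 with no filter on low counts and 151 with the DESeq2 test.

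Between the MLLT1 and MLLT6 knockouts, S100a8 was at 669 ± 80.5 CPM (n = 6) in MLLT1 and at 110 ± 56.0 CPM (n = 6) in MLLT6. Ltf was higher in MLLT1 by 2.91 ± 0.40 and Clec4a2 by 2.69 ± 0.29 (edgeR adjusted p = 5.71e-05 and 2.52e-06). Lower in MLLT1 were Tnfrsf9 (log2 fold change -4.19 ± 0.42), Hbb-bt (-2.81 ± 0.20) and Ddx4 (-2.65 ± 0.23, largest adjusted p of these, 6.75e-07). In all, 188 genes were higher and 284 lower. The count of 472 was 758 without MLLT1 guide 1 replicate 1, 311 without MLLT1 guide 2 replicate 3 and 293 without MLLT6 guide 2 replicate 2. It was 862 with no filter on low counts, 800 with the replicate number as a block and 312 in a fit of the compared groups alone.

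Genes called in the MLLT1 and MLLT10 knockouts were compared with those called in the DOT1L knockout. S100a8, Camp and Wfdc21 were higher in both the DOT1L and the MLLT1 knockout, and Tnfrsf9 and Hbb-bt lower. In all, 82 genes were higher in both, where independent lists would share 11.5. Lower in both were 129, where independent lists would share 18.1. The simulations of unchanged groups shared 0, which decides nothing, since unchanged groups leave few called genes to share. Another 9 moved in opposite directions. The correlation across genes, which are not independent replicates, was 0.63 (0.60 simulated), and the covariance was 0.344 (0.066 simulated, a difference of 0.278). For DOT1L and MLLT10, 24 genes were higher in both and 23 lower in both. Independent lists would share 2.79 and 2.67, and the 0 of the simulations again decides nothing. The correlation was 0.57, below the 0.60 simulated, and 68.1% of genes had the same sign, below the 70.2% simulated. The covariance was 0.26 (0.066 simulated, a difference of 0.195). For DOT1L and MLLT6 the difference in covariance was 0.028. The 3 control libraries cannot be split into parts of 2 or more, so part of the excess may come from the shared controls.

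**Figure D5:**
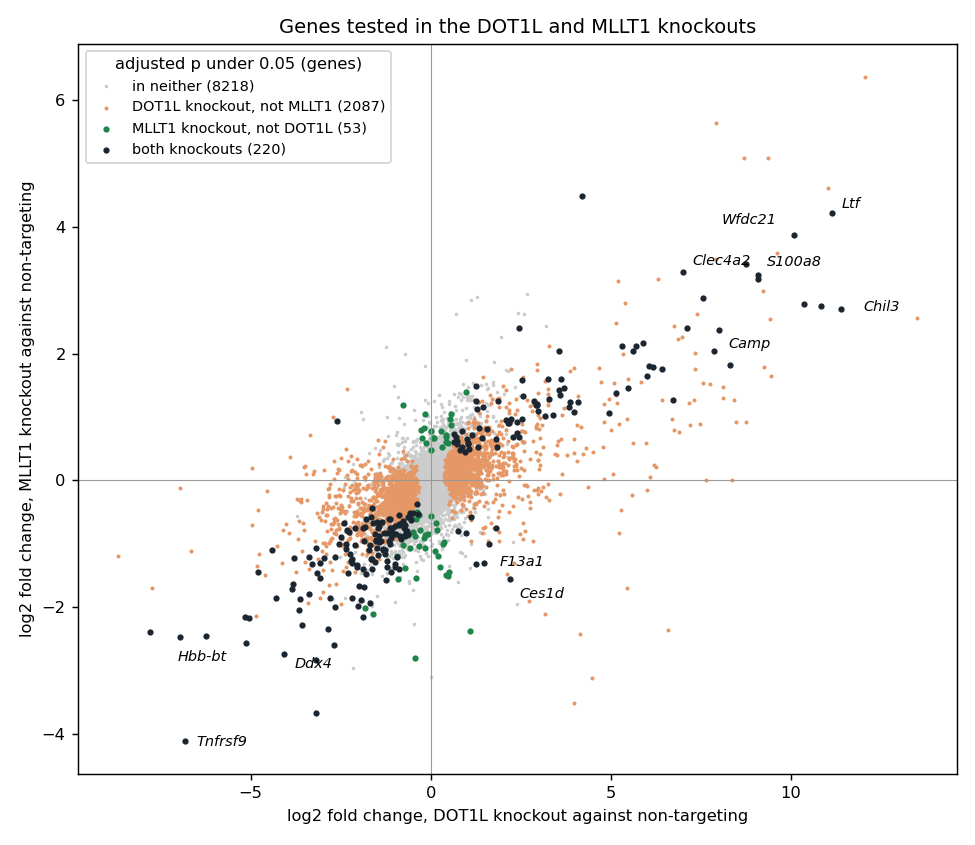
Log2 fold change against non-targeting in the DOT1L knockout (x axis) and in the MLLT1 knockout (y axis) of the 10578 genes tested, 1 point per gene, coloured by whether the adjusted p was under 0.05 in either. Of the genes called in both, 82 lie higher in both, 129 lower in both and 9 on opposite sides.

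A comparison between knockouts that leaves out the control libraries was also made. The 1181 genes that were higher in the DOT1L knockout, S100a8 and Ltf among them, lay higher in MLLT1 than in MLLT6, with a median log2 fold change of 0.21 (camera p = 1.4e-05 with an estimated correlation). The 1128 genes that were lower there, Tnfrsf9 and Hoxa9 among them, lay lower in MLLT1, with a median of -0.27 (p = 2.9e-05 with an estimated correlation). The same sets had medians of 0.14 and -0.17 between MLLT10 and MLLT6 (p = 0.00013 each with an estimated correlation).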

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

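Under the alternatives fixed before the data were examined, no called gene named in the text changed direction in any setting. Of 149 named calls, 149 were still called with DESeq2 size factors, with the DESeq2 test and with the replicate block, 143 with no filter on low counts and 136 in fits of the compared groups alone, and 28 were lost in at least 1 fit without a library. The calls for DOT1L against non-targeting and for each knockout against DOT1L stayed within 1.5 times. With no filter, counts were 192 for MLLT10, 463 for MLLT1, 80 for MLLT6, 112 and 160 for MLLT10 guides 1 and 2, 323 and 287 for MLLT1 guides, 291 and 19 for MLLT6 guides, 16, 21 and 67 between guides of MLLT10, MLLT1 and MLLT6, 272 for MLLT10 against MLLT6 and 862 for MLLT1 against MLLT6. The DESeq2 test gave 102 for MLLT10, 47 and 81 for its guides, 217 and 220 for MLLT1 guides, 47 for MLLT6 guide 1, 10 between MLLT6 guides and 151 for MLLT10 against MLLT6. With the replicate number as a block, counts were 79 for MLLT10, 457 for MLLT1, 30 and 69 for MLLT10 guides, 265 and 223 for MLLT1 guides, 434 for MLLT10 against MLLT1 and 800 for MLLT1 against MLLT6; no other count moved by over 1.5 times. The block is a reading of the data, since the labels name no pairing. Replicate numbers paired 6 of 28 pairs of groups, where each number's correlation had to exceed 0.1. None of the 6 held MLLT1 guide 1 or MLLT6 guide 1, the groups of both libraries that stood apart, and none held the DOT1L knockout. Replicate 1 correlations were below 0 only between MLLT1 guide 1 and MLLT6 guide 1 (-0.02), replicate 3 ones only in pairs with MLLT6 guide 1. Replicate 2 correlations ran from -0.24 to 0.25. Sample numbers in the library names run by replicate, and replicate 1 held the highest mitochondrial share of counts in 8 of 8 groups. This points to a structure by replicate number that the unblocked counts ignore, though the labels name no batch. Fits of the compared groups alone, which have fewer samples, gave 28 for MLLT10, 97 for MLLT1, 3 and 14 for MLLT10 guides, 22 and 32 for MLLT1 guides and 312 for MLLT1 against MLLT6. Chosen after seeing the data, leaving out both outlying libraries gave 79 for MLLT10 and 29 and 50 for its guides. With the block as well it gave 175 for MLLT10, 781 for MLLT1, 61 and 110 for MLLT10 guides, 437 and 435 for MLLT1 guides, 607 for MLLT10 against MLLT1, 136 for MLLT10 against MLLT6 and 940 for MLLT1 against MLLT6. Leaving out each library in turn gave 15 to 56 for MLLT10, 74 to 432 for MLLT1, 5 to 16 and 5 to 50 for MLLT10 guides, 37 to 265 and 44 to 215 for MLLT1 guides, 0 to 31 for MLLT6 guide 1, 0 to 1 between MLLT10 guides and between MLLT6 guides, 45 to 72 for MLLT10 against MLLT6 and 293 to 758 for MLLT1 against MLLT6. Apart from the smaller samples named, the cause was not tested. Of the 14 lists called in DOT1L, 8 in MLLT10 and 5 in MLLT1, 6, 2 and 1 held with an estimated correlation. Depth limits genes of low count: 10578 of 43629 genes were tested.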

Other observations

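Some genes moved apart between knockouts; those in this paragraph were named after their values were seen. F13a1 was higher in DOT1L (log2 fold change 1.61 ± 0.29, edgeR adjusted p = 0.0002) and in MLLT10 (1.25 ± 0.26, adjusted p = 0.0226) and lower in MLLT1 (-1.01 ± 0.26, adjusted p = 0.0315). Ces1d, a carboxylesterase, rose in DOT1L by 2.21 ± 0.36 and fell in MLLT1 by 1.56 ± 0.32. Slc2a3, a glucose transporter, rose by 1.27 ± 0.21 in DOT1L and fell by 1.32 ± 0.18 in MLLT1, and Trf, transferrin, rose by 1.47 ± 0.28 and fell by 1.30 ± 0.26 (largest edgeR adjusted p of these 3 genes in either knockout, 0.00803). Csgalnact1 went the other way, with -2.61 ± 0.35 in DOT1L and 0.94 ± 0.25 in MLLT1. The other 4 of the 9 genes were Lbh, Mgst2, Prtn3 and St3gal1, each higher in DOT1L and lower in MLLT1. Ccl9 rose in MLLT10 by 1.06 ± 0.17 and fell in MLLT1 by 1.01 ± 0.16. Of the 50 genes called in MLLT10, 3 were not called in DOT1L: Ccl9, Itm2b and Wnk1. Of the 273 called in MLLT1, 53 were not.

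Lineage lists without a common direction also held called genes in the DOT1L knockout. Of 5 erythroid and megakaryocytic genes, 3 rose and 2 fell (camera adjusted p = 0.65, direction down, with a mean log2 fold change of -0.42 and a median of 0.77), as also when adjusted over the list alone. Without non-targeting replicate 1 or any of the 3 DOT1L libraries, or in a fit of the compared groups alone, 1 fell. Pf4, a platelet chemokine, rose by 2.97 ± 0.66 and Tfrc, the transferrin receptor, by 0.77 ± 0.18, while Hbb-bt fell by 5.13 ± 0.36 (largest edgeR adjusted p of these, 0.0032). Of 3 lymphoid genes, too few for a list test, Lck fell by 1.17 ± 0.33, and Bcl11b fell by 1.95 ± 0.58 (edgeR adjusted p = 0.0125 and 0.0163). Lck did not pass without DOT1L replicate 2 (adjusted p = 0.0715), nor Bcl11b without non-targeting replicate 3 (0.07) or DOT1L replicate 3 (0.13).

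The tests in the following paragraphs were chosen after the results were seen, except those of gene length and GC content and of other splits of the libraries. Of the 273 genes called in MLLT1, 211 were called in the same direction in the DOT1L knockout and 9 in the opposite one, and of the 50 called in MLLT10, 47 were called in the same direction. RNA of DOT1L knockout cells in these libraries would bring all its neutrophil transcripts in a single share. Over 16 neutrophil granule genes, though, shares differed by gene in MLLT1 and in MLLT10 (permutation p = 0.0001 each, the smallest that the permutations run can give). The permutation takes the control mean subtracted from each gene as exact. The highest share was 160 times the lowest positive share in MLLT1 and 137 times in MLLT10. The lowest, that of Chil3 (0.068% ± 0.084 in MLLT1), was near 0 beside its SD, so these ratios have no clear size. In MLLT1, Hp stood at 11% ± 5 (SD, n = 6) of its DOT1L level, Ngp at 5.9% ± 1.2, S100a8 at 1.5% ± 0.21 and Ltf at 0.78% ± 0.22. A single share does not give all these levels, but whether a part was carried over was not tested. For the genes lower in DOT1L, a share of 1.41% of S100a8 and S100a9 would give a median of -0.011 between MLLT1 and MLLT6, and the observed median, which uses no control library and so also argues against the shared controls, was -0.268. What moves these genes together was not tested further and stays open.

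MLLT1 guide 1 replicate 1 and MLLT6 guide 1 replicate 3 differed most from the other replicates of their groups, with an SD over genes of the log2 difference of 0.65 and 0.58, against at most 0.51 in the other libraries. On the second principal component (14% of variance) they scored -48.6 and -36.6. Non-targeting replicate 3 (40.8, its group at -11.2 and 7.09) and MLLT1 guide 2 replicate 3 (30.8, its group at -6.94 and -3.03) lay further from their groups there than the MLLT6 library, whose group was at -11.9 and 5.86. Gene length and GC content gave 0.9% of the variance over genes of the MLLT6 library's difference from its group and 5.6% of the MLLT1 library's, within the 0.1% to 6.6% of the other libraries. A wrong knockout label is argued against for the MLLT1 library by its 0.102% of counts from S100a8 and S100a9. That is above the 0.065% that the highest non-targeting, MLLT10 or MLLT6 library held and far below the 6.07% of DOT1L. It is also below the 0.121% to 0.14% of the other MLLT1 libraries, so the library lies outside its own group too. For the MLLT6 library, a Mllt6 level of 14.9 CPM argues against the non-targeting, MLLT10 and MLLT1 labels, whose libraries held 22.6 to 42.2 CPM. That range overlaps the MLLT6 libraries, which reach 23.3 CPM. Mllt6 was as low in the DOT1L libraries (19.3, 19.9 and 14.1 CPM), and against that label stands the library's 0.017% from S100a8 and S100a9. No biological explanation was tested, and what sets these libraries apart stays open.

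No gene was called in the MLLT6 knockout. With both outlying libraries left out, 0 genes were called as well. That fit has fewer libraries, so it cannot exclude that the outlying MLLT6 library hid small changes. Changes under 2-fold cannot be told apart from no change, and 2-fold changes only in part. In the simulated design 14% of 1.5-fold and 58% of 2-fold changes were called. That design changed 200 genes by up to 8-fold, none of low count, which eases the adjusted threshold. With no gene called in the data, the true shares are probably lower. In the data, 727 genes lay at an unadjusted p under 0.05 where chance would give 529. Without non-targeting replicate 3 there were 258, without MLLT6 guide 1 replicate 3 there were 472, and without non-targeting replicate 1 there were 1256.

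Other splits of the same libraries were fitted with the libraries of the comparison alone and both guides of a gene pooled into 1 group, so the real counts differ from those of fits that keep the guides apart. For MLLT1 against non-targeting, 1 of 84 splits, the real one, gave as many genes (128, highest other 4). The real grouping thus stands out among the splits of these libraries. The splits cannot exclude an effect of culture or transduction, since the labels do not say that replicates came from separate cultures. The same holds for DOT1L against MLLT10 (1 of 84 splits, 2848 genes, highest other 21), against MLLT1 (1 of 84, 2020, highest other 1) and against MLLT6 (1 of 84, 3002, highest other 1), and for MLLT1 against MLLT6 (1 of 100 drawn, 401, highest other 1). For MLLT10 against non-targeting, 3 of 84 splits gave as many as the real 45. The split of all replicate 1 libraries from the others called 452, which points to a structure of the libraries by replicate number. Libraries so structured are not interchangeable, so these splits do not decide whether chance gives 45. The blocked count was 79, in all 24 libraries. Replicate 1 held the highest mitochondrial share of counts in 8 of 8 groups, between 1.62% and 2.17%, against at most 1.57% in the other libraries. For MLLT10 against MLLT1, 2 of 100 drawn splits gave as many as the real 264, and for MLLT10 against MLLT6, 3 of 100 gave as many as 67. Splits with all 4 replicate 1 libraries on the same side called 382 and 131, so for both comparisons the splits leave chance undecided. The blocked counts were 434 and 114. For MLLT6 against non-targeting the real count was 0, which all 84 splits reach by definition, so they decide nothing (highest other 98).

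With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. DOT1L against non-targeting had 2337 genes (1 split as large, highest other 0). MLLT10 guide 1 had 3 (highest other 0) and guide 2 had 14 (2 splits as large, highest other 35). MLLT1 guide 1 had 22 (highest other 0) and guide 2 had 32 (highest other 30). Both MLLT6 guides had 0 (highest other 0 and 150), as had the guides of MLLT10, MLLT1 and MLLT6 set against each other (highest other 82, 9 and 0), and all 10 splits reach a count of 0 by definition. The highest other splits of MLLT10 guide 2 and MLLT1 guide 2 against the control put replicates 1 and 2 of the control on the side of replicate 1 of the guide.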
